A study of Mus musculus with 2 samples.

How the data were processed

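Total RNA from mouse embryonic stem cells of the ES-D3 line (strain 129S2/SvPas) was profiled on Affymetrix Mouse Gene 2.0 ST arrays, which measure each transcript with probes spread along its exons. There were 2 arrays, 1 from cells grown on a 6-well plate and 1 from cells grown in a microchamber. Both cultures were seeded at 20000 cells per square centimetre and harvested after 3 days, in medium with 15% serum and 1000 U of leukaemia inhibitory factor (LIF), per the labels' protocols.

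The authors corrected the probe intensities for background, summarised them per transcript cluster (called a probe set here) and normalized them between arrays with the RMA method, per the series design text. The deposited values are on a log2 scale, per that text and the file headers. The design text also names a filter on raw signal from the 20th percentile upwards. The submitters' processing notes name Affymetrix Expression Console 1.4.1, Transcriptome Analysis Console 3.0 and RMA. The headers name the mm10 build for the probe set annotation. RMA forces both arrays to the same distribution of values, so a change that moved most genes one way would not be visible. The authors' deposited table also holds a log2 fold change, written as plate minus chamber, and its absolute fold as a ratio with no direction. For all 33793 probe sets the deposited log2 fold change equalled the plate value minus the chamber value within 1e-05. The value table of the series and the authors' table held the same log2 values. Every difference given here is turned the other way, as microchamber minus 6-well plate.

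Of the 33793 probe sets, 24708 carried 1 gene symbol in the authors' table, 2305 carried several, 6756 carried none and 24 carried a symbol that spreadsheet software had turned into a date. Only probe sets with 1 symbol entered the comparison, and probe sets of the same gene were averaged. This gave 23370 genes, of which 1063 had more than 1 probe set and 20206 had a symbol that is current in the RefSeq gene table for GRCm38. Gene coordinates are those of the whole gene in that table, which has the same build as the array annotation. A gene was kept when its higher array lay at or above the 20th percentile of probe sets with a symbol on that array, which was 5.16 on the plate array and 5.17 on the chamber array. This left 19180 genes.

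With 1 array per group no test of the conditions can be made, so no p-value, standard error or count of significant genes is given. Each value describes these 2 arrays. Genes at least 1 log2 unit (2-fold) apart were counted. For each gene the number of the 1000 genes nearest to it in mean level that differed by at least as much was also taken. The genes in the text follow a rule fixed before the data were examined. It takes the 12 highest and 12 lowest differences among genes at or above the median of probe sets with a symbol on their higher array, leaving out predicted, unnamed, microRNA, small nucleolar RNA, olfactory and vomeronasal receptor, histone and pseudogene symbols. It adds 17 genes fixed by name, and up to 4 members of each gene list that lay outside its random lists, taken in the direction of the list median. Genes named outside the rule are said to be so.

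A total of 37 gene lists were fixed at the same stage, and 7 more lists were added after seeing the data for the closing observations. The median difference of a list was set against the medians of 10000 random lists of the same size, matched on mean level in 20 bins of equal size, and given as a percentile among them. A list was said to lie outside the random lists with a percentile under 2.5 or over 97.5, and lists needed 8 members past the filter. Genes that share a regulator move together, which random lists do not copy, so a percentile describes these arrays and is not a p-value. Of 37 lists, 1.85 would lie outside by chance if their genes were independent. The list calculation was tested on simulated data, in which differences of the 19180 genes were shuffled within bins of mean level. Among 200 lists of 20 genes with no planted shift, each set against 2000 random lists, 2.0% lay above the upper bound and 2.0% below the lower bound. A planted shift of 0.1 log2 units was found in 46.0% of 200 lists and a shift of 0.25 in 100.0%. The simulated lists were drawn from genes of all levels. Differences spread more widely at higher levels, so these shares may be too high for lists of well-expressed genes.

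The alternatives were no filter, a filter at the median, differences centred on their median, removal of a loess trend of difference on mean level (span 0.3), the brightest probe set of a gene, the authors' table as the source, shared probe sets under their first symbol, other fold thresholds, 10 bins, lists without genes of another list, random lists without predicted genes, and the mean of a list in place of its median. Random lists matched on genomic length as well, which spans introns, in 10 bins of mean level with 3 bins of length each, were added after seeing the data, and 95.9% of genes past the filter had a length. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. Scanner files were not used here, so signal over background per probe and alternative background corrections were not examined. Precision is limited by the number of arrays.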

Results

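Gene expression of ES-D3 mouse embryonic stem cells was compared between a standard 6-well plate and a microfluidic chamber run with little perfusion. ES-D3 is an established pluripotent line kept undifferentiated with LIF. The comparison asked how confinement in the chamber alters expression, with endogenous LIF named in the study title. Each condition had 1 array and no replicate. Values are log2 RMA values, and differences are microchamber minus 6-well plate, the opposite sign to the authors' deposited fold changes.

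The arrays were close to each other. The values correlated at r = 0.99 across the 23370 genes, which are not independent replicates. The median of all probe sets was 5.82 on both arrays, with a range of 4.58 to 13.73 on the plate array and 4.60 to 13.71 on the chamber array. Among the 19180 genes past the filter, the middle 95% of differences lay between -0.61 and 0.58, with a median of -0.01. Differences at low signal were narrower, with a standard deviation of 0.13 in the lowest of 4 equal groups by mean level and 0.35 in the highest. For 797 genes with 2 distinct probe sets past the filter, the microchamber minus plate difference of 1 probe set had a within-gene standard deviation of 0.21. The 1348 olfactory and vomeronasal receptor genes, which are sensory receptors, had a standard deviation of 0.09 without the filter. These values measure the spread within this pair of arrays, not between cultures.

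In the microchamber 66 genes were at least 2-fold higher and 85 were at least 2-fold lower. The lowest were led by genes of the response to low oxygen. Bnip3, a mitophagy receptor on chromosome 7 (138890836 to 138909506, GRCm38), had 10.21 on the plate and 7.37 in the chamber, which is 7.15-fold lower. Egln3, an oxygen-sensing prolyl hydroxylase on chromosome 12 (54178981 to 54203874), was 6.80-fold lower, and Ddit4, an inhibitor of mTORC1 on chromosome 10 (59949675 to 59951770), was 5.70-fold lower. No gene among the 1000 nearest in mean level differed as much as Bnip3 or Egln3, and 1 did for Ddit4. The highest were the immediate early transcription factors Egr1 on chromosome 18 (34861207 to 34864956), which was 5.98-fold higher, and Fos on chromosome 12 (85473890 to 85477274), which was 5.48-fold higher.

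**Figure D1:**
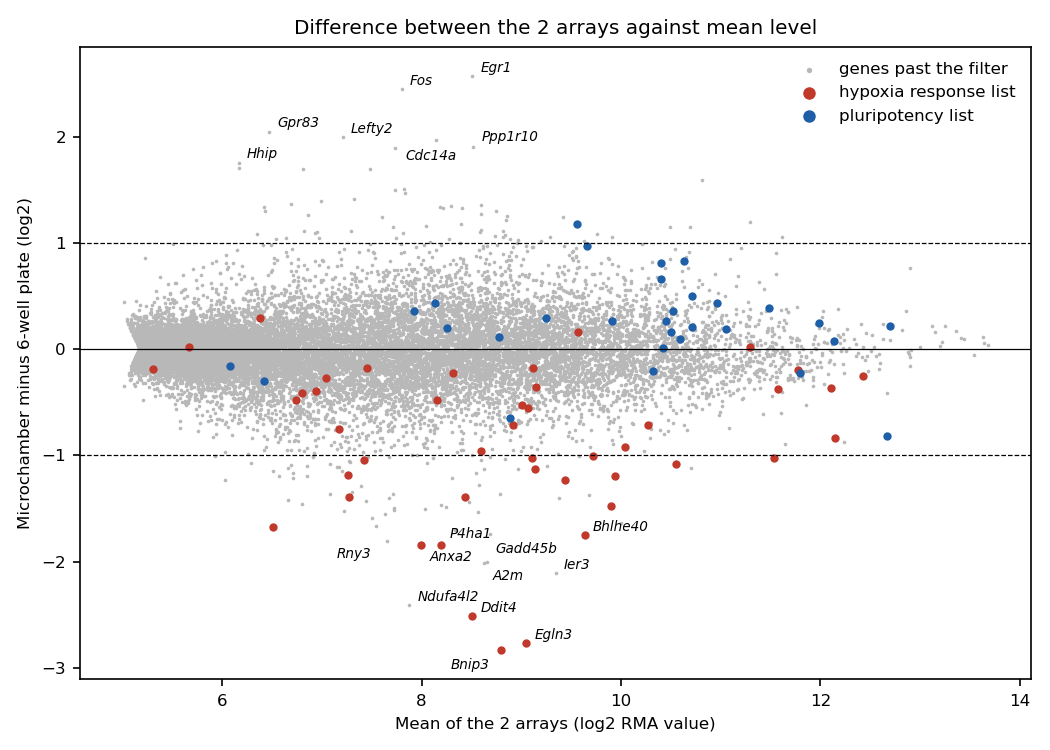
Difference between the arrays (microchamber minus 6-well plate, log2) against the mean of both (log2 RMA value) for the 19180 genes past the filter, 1 point per gene, with dashed lines at 2-fold. Of the 45 hypoxia response genes (red) 41 lie below 0, and of the 30 pluripotency genes (blue) 24 lie above 0.

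The hypoxia response list was lower in the microchamber almost throughout. Of its 45 measured members, 19 were at least 2-fold lower, none was 2-fold higher, and 41 lay below 0. The list median was -0.75, against -0.12 to 0.07 for the middle 95% of matched random lists, and it lay below all 10000 of them (percentile 0). Besides the genes above, Anxa2, a membrane-binding annexin, was 3.58-fold lower, P4ha1, a collagen prolyl hydroxylase, was 3.58-fold lower, and the transcriptional repressor Bhlhe40 was 3.37-fold lower. Several members were picked after their values were seen: the glucose transporter Slc2a1 at -0.71, the glycolytic enzymes Ldha at -0.96 and Pgk1 at -0.83, the angiogenic factor Vegfa at -1.02, and the only 4 members above 0, which were Nrn1 at 0.02, P4hb at 0.02, Kdm3a at 0.16 and Pfkfb4 at 0.30. The probe sets of Ndrg1, another member singled out afterwards, were unequal at -0.73 and -2.06.

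Lists of cholesterol synthesis and mitochondrial respiration were lower by smaller amounts. Of 32 cholesterol synthesis and SREBP target genes, 29 lay below 0 and none reached 2-fold, with a median of -0.25 at percentile 0.02. Sc4mol and Hmgcs1, enzymes of the sterol pathway, were at -0.70 and -0.62, Acss2, which makes acetyl-CoA from acetate, was at -0.65 and the sterol-sensing regulator Srebf2 was at -0.56. Of 80 nuclear genes taken by symbol pattern as oxidative phosphorylation genes, 62 lay below 0, with a median of -0.16 at percentile 0.02. Its lowest member, Ndufa4l2, was 5.32-fold lower and is known as a hypoxia-induced gene; the next were Ndufv3 at -0.96, Cox7a1 at -0.93 and Atp5s at -0.81. The ATF4 target list of amino acid deprivation (median 0.03, percentile 85.6), the endoplasmic reticulum chaperones (0.05, percentile 85.0), heat shock genes (-0.16, percentile 4.23), p53 targets (0.02, percentile 75.3) and NRF2 targets (-0.05, percentile 29.2) lay within the random lists.

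Pluripotency genes were modestly higher in the microchamber. Of 30 genes on the list 24 lay above 0, and the median of 0.24 lay above all 10000 random lists (percentile 100). Tcl1, a co-activator of AKT, was 2.27-fold higher and the only member past 2-fold. The orphan receptor Nr5a2 was at 0.97, the transcription factor Tbx3 at 0.83 and the transcription factor Klf2 at 0.81. The core factors differed less, with Pou5f1 (Oct4) at 0.36, Sox2 at 0.25, Nanog at 0.08, Klf4 at 0.37, Esrrb at 0.20 and Zfp42 (Rex1) at 0.22. Of the 1000 genes nearest in level, 755 differed by at least as much as Nanog and 263 by at least as much as Pou5f1. Among members below 0, singled out afterwards, the Nodal co-receptor Tdgf1 was at -0.82 and the RNA-binding protein Lin28a at -0.65.

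Lif itself, on chromosome 11 (4257568 to 4272514), had 6.44 on the plate and 6.84 in the chamber. This difference of 0.41 is 1.33-fold, and 177 of the 1000 genes nearest in level differed by at least as much. Its receptor chains were at 0.60 for Lifr and 0.14 for Il6st, the shared gp130 subunit. The 13 measured LIF family ligands and receptors past the filter had a median of 0.00 at percentile 57.8. The list of LIF and STAT3 response genes went the other way, with 15 of 25 members below 0, 3 at least 2-fold lower and none 2-fold higher. The survival gene Ier3 was 4.31-fold lower, the adhesion receptor Icam1 2.65-fold lower and the nuclear factor kappa B regulator Bcl3 2.19-fold lower. Socs3, the feedback inhibitor of LIF signalling, was 1.93-fold lower, and its 2 probe sets were at -0.98 and -0.92. The 10 members above 0 included Myc at 0.97 and Klf4 at 0.37. This list's median of -0.13 lay just outside the random lists at percentile 2.35 and was inside at 2.56 after centring and at 3.06 against random lists without predicted genes. Klf4 and, named outside the rule, Klf5 and Tfcp2l1 are on both this list and the pluripotency list.

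**Figure D2:**
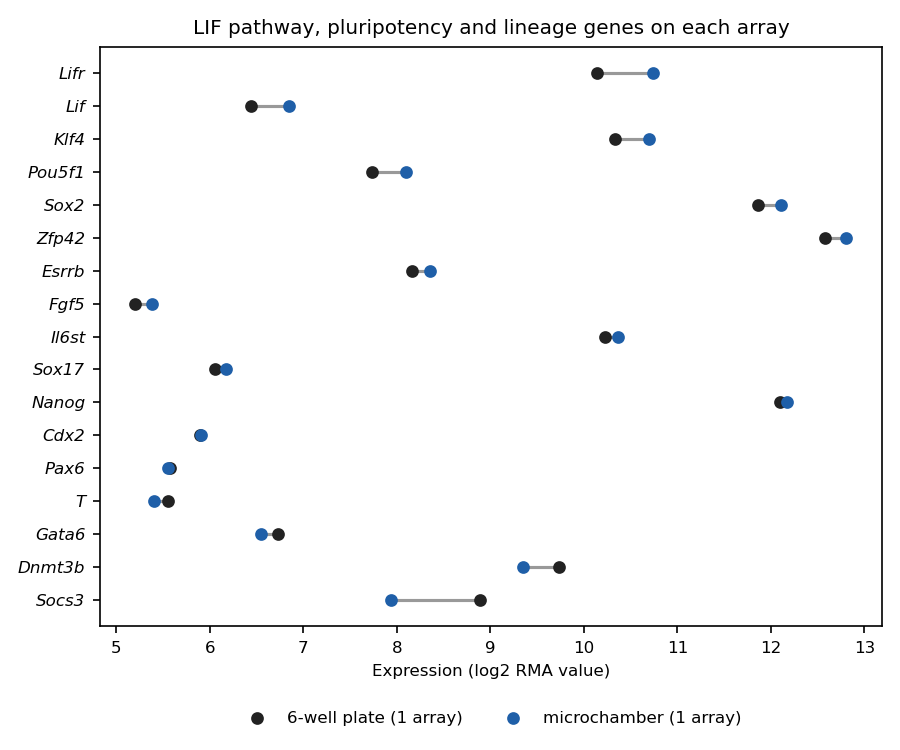
Expression (log2 RMA value) of the 17 genes fixed by name on the 6-well plate array (black) and the microchamber array (blue), 1 array each, ordered by difference. Lifr at 0.60 had the largest positive difference and Socs3 at -0.95 the largest negative one.

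Feedback targets of fibroblast growth factor and ERK signalling were higher in the microchamber. Of 21 measured members 16 lay above 0, 2 were at least 2-fold higher and none was 2-fold lower, with a median of 0.22 at percentile 99.9. Besides Egr1, the MAP kinase phosphatase Dusp4 was 2.53-fold higher, Myc, a growth-promoting transcription factor, was at 0.97 and the ephrin receptor Epha2 at 0.80. The 5 members below 0 included, outside the naming rule, Etv4 at -0.55 and Fgfr1 at -0.30. Egr1 and Myc are also on the immediate early list. The other 19 members had a median of 0.14 at percentile 98.0, just past the bound. The immediate early list was split. It had 4 of 28 members at least 2-fold higher (Egr1, Fos, Ier2 and Arc, the last pair outside the naming rule at 1.30 and 1.18) and 2 at least 2-fold lower (Ier3 and the stress gene Gadd45b, which was 9.66 on the plate and 7.66 in the chamber). Its median of 0.07 lay within the random lists at percentile 93.3. Dusp9, another MAP kinase phosphatase but on neither of these lists, was 3.26-fold lower.

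Secreted signals differed in both directions. Among 54 growth factor and cytokine ligands, 5 were at least 2-fold higher and 1, Vegfa at -1.02, was at least 2-fold lower, with a median of 0.00 at percentile 62.0. Lefty2, a Nodal antagonist on chromosome 1 (180893108 to 180899107), had 6.21 on the plate and 8.21 in the chamber, and Kitl, the ligand of the Kit receptor, was 2.59-fold higher. The other 3, outside the naming rule, were Bmp4 at 1.20, the activin antagonist Fst at 1.05 and Lefty1 at 1.04. The Nodal and TGF-beta target list had a median of 0.11 at percentile 96.3, within the random lists, and it passed the bound at 99.5 with the filter at the median. BMP and SMAD1 targets (-0.04, percentile 32.2) and WNT targets (0.02, percentile 79.3) lay within the random lists. The BMP list had 2 members at least 2-fold higher and 1 at least 2-fold lower. Id4, an inhibitor of helix-loop-helix factors on that list, was 3.25-fold higher, while Dusp9, also on it, was 3.26-fold lower.

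Lineage lists did not lie outside the random lists. Their medians were 0.04 for primitive endoderm and endoderm (percentile 91.3), -0.01 for primitive streak and mesoderm (percentile 55.4), -0.04 for neural and ectoderm (percentile 20.0), -0.04 for trophectoderm (percentile 27.6) and -0.12 for primed epiblast (percentile 6.91). Gata6 was at -0.17, Sox17 at 0.11, T (Brachyury) at -0.15, Pax6 at -0.03, Cdx2 at 0.01, Fgf5 at 0.18 and Dnmt3b at -0.38. T, Pax6, Cdx2 and Fgf5 lay below the median of probe sets with a symbol on both arrays. Differences are compressed at low signal, so their small values do not show unchanged expression. Trophectoderm, with 2 of 19 members at least 2-fold lower (Ascl2 at -1.43 and Krt19 at -1.34, both outside the naming rule), and primed epiblast passed the lower bound under some settings, at percentile 0.01 and 0.43 with the filter at the median. The endoderm list passed the upper bound at percentile 98.4 without genes of another list and at 99.7 for the mean. Cubn, an endocytic receptor of visceral endoderm, was 2.78-fold higher. The 2-cell-like list had a median of -0.06 at percentile 15.2.

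Germline genes were lower, with 18 of 21 members below 0 and a median of -0.14 at percentile 0.74, which was 8.94 with the filter at the median. Mael, a piRNA pathway protein, was 2.88-fold lower, the germ cell helicase Ddx4 was at -0.90, and Tdrd12 and Syce1, which act in the piRNA pathway and in meiotic chromosome pairing, were both at -0.71. Of 41 genes of G2/M and mitosis 32 lay below 0 and none reached 2-fold, with a median of -0.16 at percentile 0.37. The ubiquitin ligase G2e3 was at -0.96, the kinesin Kif23 at -0.70, the phosphatase Cdc25c at -0.49 and Hmmr at -0.45. The G1/S and replication list was at -0.10 (percentile 6.87). Genes of YAP, actin and shear response had a median of -0.15 at percentile 0.46, with 24 of 34 below 0. The members below 0 included the actin-binding calponins Cnn1 at -1.01 and Cnn2 at -0.76, Anxa3 at -0.99 and Tagln2 at -0.62. The 10 members above 0 included Klf2 at 0.81 and, outside the naming rule, Ctgf at 0.30 and Cyr61 at 0.07. The extracellular matrix list was at -0.04 (percentile 37.0).

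Fibroblast and feeder cell markers were lower, with a median of -0.14 at percentile 0.74 and 15 of 21 below 0; the percentile was 8.97 without the filter and 2.96 for the mean. Pdgfrb was at -0.49, Twist2 at -0.48, Acta2 at -0.41 and Twist1 at -0.35. The chamber value of Twist2, 5.30, lay close to the 20th percentile of 5.17. Acta2 and, named outside the rule, Tagln are also on the actin list, and several collagens are also on the extracellular matrix list. Endothelial and blood markers (-0.02, percentile 43.2) and muscle markers (-0.05, percentile 28.1) lay within the random lists.

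**Figure D3:**
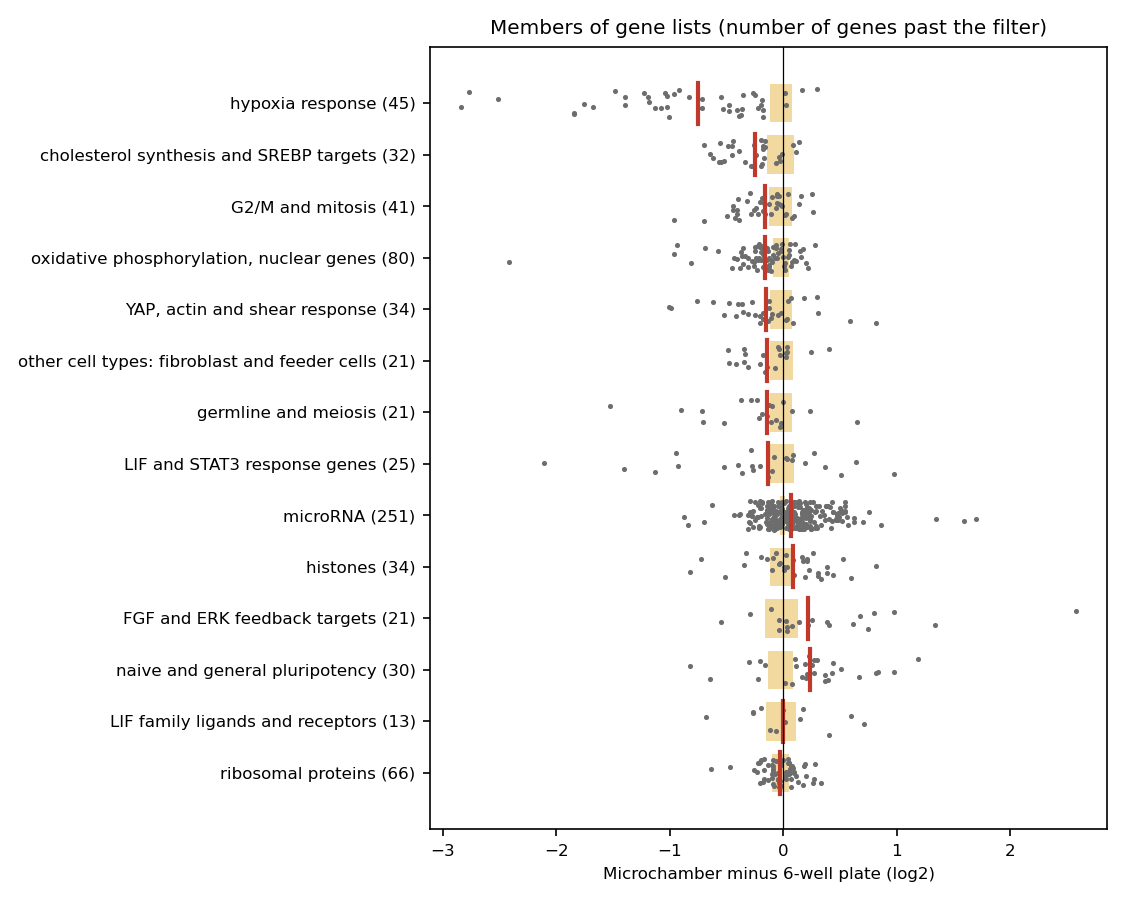
Differences (microchamber minus 6-well plate, log2) of the members of the 12 lists outside the random lists, with 2 lists inside them at the bottom, 1 grey point per gene past the filter. Red lines are list medians and yellow boxes span the middle 95% of 10000 matched random lists; the hypoxia median of -0.75 lies farthest from its box.

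Among the other genes with the largest differences, the higher ones were the orphan receptor Gpr83 (4.15-fold), the phosphatase regulator Ppp1r10 (3.74-fold), the phosphatase Cdc14a (3.74-fold), the hedgehog-binding protein Hhip (3.39-fold), the cysteine dioxygenase Cdo1 (2.84-fold) and the transcription factor Spic (2.67-fold). The plate values of Gpr83 and Hhip, 5.44 and 5.28, lay close to the 20th percentile of 5.16, so their folds are taken against low signal. The lower ones were the protease inhibitor A2m (4.05-fold) and the Y RNA Rny3 (3.50-fold), a short non-coding RNA.

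RNA classes were also examined. Ribosomal protein genes, 66 in number, had a median of -0.02 at percentile 50.4. Small nucleolar RNA genes were at 0.02 (percentile 89.4), and olfactory and vomeronasal receptors past the filter were at 0.01 (percentile 90.1). The receptors passed the upper bound at 97.8 against random lists without predicted genes and at 98.7 for the mean. With the filter at the median they were at 99.5, with 28 genes left and a median of 0.11. A small median past the bound therefore does not by itself show a change of a whole class. Probe sets named for microRNA genes, which cover hairpin or precursor sequence, were higher, with 152 of 251 above 0 and a median of 0.07 above all 10000 random lists (percentile 100). With the filter at the median, the microRNA median was 0.11, about that of the receptors, and the list stayed at percentile 100. Mir1192 was 3.25-fold higher, Mir290 3.02-fold, Mir18 2.54-fold and Mir30e 1.81-fold. The plate value of Mir30e, 4.80, lay below the 20th percentile of 5.16, so its fold is taken against a value near the floor. Of 34 histone genes 22 lay above 0 and 12 below, with a median of 0.09 at percentile 98.9. The list fell inside the random lists at 94.0 when shared probe sets were included under their first symbol. It was also inside at 96.3 with the filter at the median and at 95.8 for the mean. Hist1h2bh was at 0.81, Hist1h4i at 0.60, Hist1h2al at 0.53 and Hist2h2ac at 0.44. The plate value of Hist1h2al, 5.21, also lay near the floor. Histone genes are near-identical copies, so signal may be shared among them. The 10 mitochondrial genome genes had a median of 0.14 at percentile 96.9, with list medians of 13.21 and 13.40 on the plate and chamber arrays, near the highest values of both.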

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

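The tests on the medians without the loess trend, on the size of the nuclear-retained list, on lineage genes, on the other immediate early genes and on ERK feedback targets, and the match on genomic length, were chosen only after the results they concern had been seen. The second hypoxia list and the list of nuclear-retained transcripts were fixed before their values were seen, but after the main result. Apart from Egr1, Fos and Myc, the genes named in this part are outside the naming rule and were chosen after their values were seen.

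Among probe sets without a gene symbol, 34 were at least 2-fold higher in the microchamber and 5 at least 2-fold lower. A signal stood out in 9 consecutively numbered unnamed probe sets, 17514328 to 17514352, which were all higher, by 1.61 to 2.73 with a median of 2.10. Another 13 unnamed probe sets, 17532605 to 17532647, numbered between those of named mitochondrial genes, were all higher, by 0.24 to 1.90 with a median of 1.09. Of the unnamed probe sets just outside these limits, 17532593 was at 1.91 and 17532653 at -1.15. What these probe sets measure was not worked out here.

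The hypoxia list lay below all of its random lists, and its median was -0.75 before and -0.71 after the loess trend was removed. Little trend was there to remove, since median differences of equal groups by mean level lay between -0.04 and 0.00. This argues against an intensity-dependent difference left in the deposited values as the whole cause. An effect of the normalization itself was not tested, and removing so small a trend could not test it. A gene length bias between the RNA preparations stays open: the list was at percentile 0 among random lists matched on genomic length, but that length spans introns, and transcript length was not used here. A weaker hypoxia response in the microchamber (biological) remains as a hypothesis: a second list of hypoxia genes had 23 of 29 members below 0, a median of -0.30 and percentile 0. Not all such genes go along, since Wsb1 on that list was at 0.92, and Cited2, a known target of hypoxia-inducible factor left off the list because its value had been seen, was at 1.15. Culture vessel, harvest and RNA preparation all differed along with the condition, which had 1 array each.

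The median of the higher pluripotency list was 0.24 before and 0.28 after the loess trend was removed. This argues against an intensity-dependent difference left in the deposited values as the whole cause, while an effect of the normalization itself was not tested. A gene length bias between the RNA preparations stays open here too, at percentile 100 with the same match. A lower share of differentiated cells in the microchamber stays open: 51 lineage genes at or above the array median were at percentile 55.0, with 23 above 0 and 28 below, and the written bound of 50 against it was met but set aside after the result was seen, because a median near 0 over members that go both ways decides nothing. Fibroblast markers were at percentile 0.74, but at 8.97 without the filter and 2.96 for the mean. Trophectoderm and primed epiblast were at 27.6 and 6.91, and at 0.01 and 0.43 with the filter at the median. Endoderm was at 91.3, and at 99.7 for the mean. A direct effect of the chamber on the pluripotency genes, the difference the design names, was not tested apart from these.

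Egr1 and Fos were higher by 2.58 and 2.45. A larger share of nuclear or unspliced RNA in the microchamber preparation stays open. A list of nuclear-retained and detained-intron transcripts was higher, at percentile 99.7, above the upper bound, as this explanation would have it. MicroRNAs were at 100 and small nucleolar RNAs, also nuclear, at 89.4. The members of that list were shifted by less than Egr1 and Fos. Their median was 0.15 with a standard deviation of 0.35 over 29 members, 11 of them below 0. The highest member, Ccnl1, was at 1.02. That comparison of sizes was chosen only after the list had been seen to be higher, so it does not decide the question. Higher ERK activity in the microchamber (biological) stays open, since the 19 feedback targets that are not immediate early genes, at percentile 98.0, are the list already seen to be higher without Egr1 and Myc. Handling at harvest could not be decided, since the other 26 immediate early genes had a median of 0.03 at percentile 80.3. Of these, 13 lay above 0, with Ier2 at 1.30 and Arc at 1.18, and 13 below, with Jun at -0.33 and Zfp36 at -0.52.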

How the results depend on the processing

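With 1 array per condition no replicate can be left out, and every alternative is a description of the same pair of arrays. Of 442 list values under alternatives, 415 stayed on their side of the bounds, 8 moved inside and 19 moved outside, and none turned. Of 37 lists, 22 stayed on their side throughout; among them hypoxia stayed at percentile 0 and pluripotency and microRNA at 100, cholesterol synthesis ranged from 0 to 0.02 and FGF and ERK feedback from 99.0 to 100. Of 567 values of named genes, 566 stayed on their side of 2-fold, and Cnn1 moved to -0.97 without the loess trend. The filters cannot change the difference of a gene, and the authors' table gave identical values for genes and lists alike. Those agreements were fixed in advance and say nothing of stability. Centring took off a median of only -0.005. The counts of 66 higher and 85 lower became 472 and 529 at 1.5-fold and 12 and 17 at 3-fold, by construction, and 74 and 74 without the loess trend, which moved the share of higher genes from 43.7% to 50%. The causes of the following moves were not tested. Without the filter the 2-cell-like list went to percentile 1.28 and fibroblast markers to 8.97. With the filter at the median, primed epiblast went to 0.43, trophectoderm to 0.01, germline to 8.94, Nodal targets to 99.5, histones to 96.3 and olfactory receptors, with 28 genes left, to 99.5. Centring moved the LIF and STAT3 list to 2.56, and random lists without predicted genes moved it to 3.06 and olfactory receptors to 97.8. Without the loess trend Nodal targets went to 97.9. The brightest probe set moved mitochondrial genes to 97.8, and first symbols moved histones to 94.0. Without genes of another list, endoderm went to 98.4 and trophectoderm to 1.35. The mean in place of the median moved primed epiblast to 1.36, ligands to 99.9, endoderm to 99.7, trophectoderm to 0, heat shock to 1.25, G1/S to 1.93, immediate early genes to 98.4, Nodal targets to 99.9, fibroblast markers to 2.96, histones to 95.8 and olfactory receptors to 98.7. Matching on genomic length, added after seeing the data, moved no list across a bound. Near the floor differences are compressed: receptor genes had a standard deviation of 0.09.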

Other observations

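The groups and genes in this part, apart from Mir290, were picked after their values had been seen. Genes with a Zfp symbol, mostly zinc finger transcription factors, were higher in the microchamber, with 217 of 347 above 0, a median of 0.11 and percentile 100 among matched random lists. The members at least 2-fold higher were Zfp59 at 1.35, Zfp84 at 1.13, Zfp119a at 1.09 and Zfp719 at 1.05. Genes of major histocompatibility class I and its peptide loading were lower, with 12 of 16 below 0, a median of -0.17 and percentile 0.49. Among them the peptide transporter Tap1 was at -0.87 and H2-K1 at -0.71, while B2m, the shared light chain, was at 0.32.

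Some probe sets shared by several genes had large differences and could not be given to 1 gene. The probe set shared by Mir291a, Mir292 and neighbouring microRNAs was at 1.62, while Mir290 alone was 3.02-fold higher. The probe set of Mat2a, which makes S-adenosylmethionine, with an overlapping transcript was at 1.60. The probe sets of Pgm2 with Itgb3bp and of Ankrd37 with Lrp2bp were at -2.13 and -1.91; Ankrd37 was on the hypoxia list but did not enter it for this reason. A second Y RNA, Rny1, was at -1.37.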
